A study of Mus musculus with 2 samples.

How the data were processed

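H3K9me3, a histone mark of silenced chromatin, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in LSK cells, the lineage-negative, Sca-1 and c-Kit positive bone marrow fraction that holds haematopoietic stem and progenitor cells. There were 2 libraries, 1 from control mice and 1 from conditional knockout mice that had lost the 3 histone demethylase genes Kdm4a, Kdm4b and Kdm4c. Both kinds of mice received tamoxifen, and cells were sorted 2 weeks later, per the labels' protocols. The groups were taken from the genotype label of each sample.

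The submitters' processing notes name Trimmomatic, Bowtie2 and the mouse build mm10, with no versions or settings. The program that called the regions and counted the reads, the width of the counting window and the handling of duplicate and multiply mapped reads are not given in the sources used here. The deposited file analysed here is a table of 1381 H3K4me3 regions (a mark of active start sites), each with its nearest gene, its distance to that gene's start site and 1 H3K9me3 value for each library. The H3K4me3 libraries are not among the samples analysed here, and 11 further columns of the region caller were not used.

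The H3K9me3 values were deposited by the authors as normalized values, read here as RPM (reads scaled to library size). The control values are whole multiples of 0.0405 RPM and the knockout values of 0.0384 RPM. All values (100.0% in each library, with a tolerance of 0.01 reads) came out as whole reads. The steps correspond to totals of 24673463 reads for the control and 26061344 for the knockout, each whole to within 1.1e-08, so these were taken as the library totals behind the scaling; values scaled to a window of 1 kb would look the same. The deposited ratio of the knockout to the control value equalled the ratio recomputed from both columns to within 4.8e-14. The lowest deposited ratio was 2.01 and no region had 0 control reads, so the table is a selection: regions with a ratio of 2 or less, or with no control read, are not in it. Region heights were deposited by the authors as H3K4me3 RPKM (reads normalized to length and depth), and these were used only to describe and rank regions within the table.

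Deposited region widths equal end minus start, so positions were read as half-open and are given 1-based on mm10. All 1381 regions were matched to the RefSeq gene table of assembly GRCm38.p6, 1376 of them by transcript accession and the rest by name. The listed start site equalled the outer 5′ end of that table's gene for 735 regions (53.2%), and the others use another start site of the gene or another annotation. In 1 row the gene symbol had been turned into a date, and the symbol was restored from the accession. The annotation used here gives genes but not exons, introns or UTRs.

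With 1 library per group there is no spread between replicates, no test between conditions and no p-value. Each region's ratio was given with an exact 95% interval from the binomial distribution of its knockout reads among its reads in both libraries, scaled by the library totals (Clopper-Pearson limits). These intervals compare 2 libraries and cover counting error only, because reads without molecular identifiers are not independent molecules. They also take no account of the selection on the ratio, which makes ratios in the table too high on average. For summaries, log2 ratios were computed after adding 0.0405 RPM (the 5th percentile of the nonzero values) to both libraries. In regions with few reads this gives a smaller log2 ratio than the deposited ratio would, but does not correct for the selection.

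Before the data were examined, 20 gene lists were fixed, together with the rule for named genes: Kdm4a to Kdm4d, Taf1b and Nom1; the 10 highest and the 10 lowest log2 ratios among regions whose mean H3K9me3 was at or above the median (1 region per gene); and the highest and lowest member of each list with at least 5 listed genes. Other genes, named beside the count of their list or for their high level (Atf7ip and Aim2 among them), were chosen after their values were seen. A gene that the rule names is not reported here. Where a gene had several regions, the one nearest its start site stood for it in list summaries. Each list's median log2 ratio was placed among 10000 random lists of the same size drawn from the table and matched on mean H3K9me3 in 10 bins. The share of each list's genes with a listed region was given with an exact (Clopper-Pearson) 95% interval. Only part of all genes could enter the table, so these shares were set beside, but not tested against, the share among all 21900 RefSeq protein-coding genes.

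To account for the selection, the knockout reads of each region were modelled as binomial given the region's total reads, limited to outcomes with a ratio above 2 and at least 1 control read, and 1 fold common to all regions was fitted by maximum likelihood, with its range from the profile likelihood. On simulated tables of 897 regions with a fold of 1, 2 or 4, the median fitted folds of 40 tables were 1.02, 1.99 and 4.02. The range of the fit held the true fold in 37, 36 and 37 of the 40 tables. These tables were drawn from the fitted model itself, with 1 common fold and counting error only. They therefore check the fitting and not how well its range holds where folds differ between regions. Alternatives were other scalings, pseudocounts, folds, filters, windows, matching and interval levels. Leaving out replicates was not possible. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.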

Results

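The study addressed where H3K9me3 lies in LSK cells with and without Kdm4a, Kdm4b and Kdm4c, whose products remove methyl groups from this mark. The data were 1 H3K9me3 library of control cells and 1 of knockout cells, with 24673463 and 26061344 reads behind the scaling. Values were analysed for 1381 H3K4me3 regions of 1296 genes, each centred within 1 kb of a listed start site. The regions lay on 19 autosomes and the X chromosome and had a median width of 680 bp (quartiles 481 and 946). Their centres lay within the gene in 769 cases, upstream of it in 600 and downstream in 12.

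H3K9me3 was higher in the knockout than in the control library at all 1381 regions, a property by which the table was assembled, since its lowest ratio was 2.01. The median ratio was 2.998 (quartiles 2.84 and 4.42) and the highest was 30.3, at Fpgt, which encodes an enzyme of fucose salvage. Levels were low in absolute terms. A region held a median of 2 control reads (quartiles 1 and 3) and 6 knockout reads (quartiles 4 and 10), and 640 regions (46.3%) held a single control read. No input library (chromatin without immunoprecipitation) is among the samples analysed here. These counts therefore do not show whether H3K9me3 in a region lay above background in either library. Summed over the table, 3379 control reads stood against 12255 knockout reads, an RPM ratio of 3.43 (95% counting interval 3.31 to 3.57).

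For 292 regions of 281 genes (21.1% of the regions), the counting interval of the ratio lay above 1, and for 48 it lay above 2. If the rates had been equal and the same selection on the ratio applied, 154 regions would have been expected to reach an interval above 1 by counting error alone. This number keeps each region's total reads as observed. How many regions, and with which totals, would pass the selection under equal rates is not known here. Under the rule set for size (a fold of at least 2 after adding the pseudocount, and a mean at or above the median), 599 of 704 regions were higher in the knockout and 0 lower. The second count could not have been above 0 in this table. The median log2 ratio after adding the pseudocount was 1.26 (quartiles 0.94 and 1.55). Scaling both libraries to the same sum over the table moved this median to -0.13, a shift of the kind that a table holding only ratios above 2 forces, so all ratios are given as deposited. With 1 library per group, none of these differences can be set against the spread between animals.

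**Figure D1:**
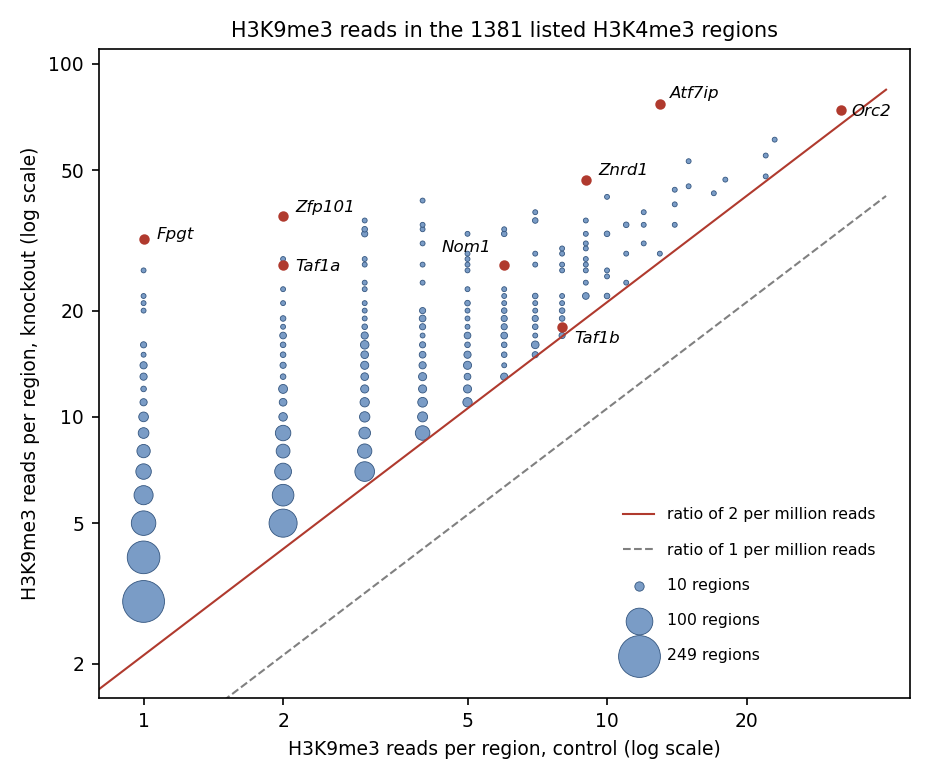
H3K9me3 reads in each listed region, with control reads on the x axis and knockout reads on the y axis (both log scales); circle area follows the number of regions with the same pair of values, the red line is an RPM ratio of 2 and the dashed line an RPM ratio of 1. Red points mark named genes, all centres lie above the red line, the largest (249 regions) stands for 1 control and 3 knockout reads, and Atf7ip reaches 77 knockout reads.

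Among regions with a mean at or above the median, the 10 genes with the highest log2 ratios after adding the pseudocount were Fpgt, Ubxn2a, Zfp101, Bola1, Snapc1, Irgm2, Il3ra, Taf1a, Crlf2 and 1700028E10Rik, the last of them tied with Rwdd1 and placed first by alphabetical order. At Fpgt (chromosome 3, 155092351 to 155093274, within the gene), 1 control read stood against 32 knockout reads, a ratio of 30.3 (5.06 to 1234). At Zfp101, a zinc finger gene (chromosome 17, 33394486 to 33394909), 2 reads stood against 37, a ratio of 17.5 (4.52 to 150). Snapc1, a subunit of the complex that activates small nuclear RNA genes (chromosome 12, 73964110 to 73965316), had 1 and 21 reads, a ratio of 19.9 (3.20 to 822). The interferon-inducible GTPase gene Irgm2 (chromosome 11, 58214362 to 58214761) had 1 and 20 reads, a ratio of 18.9 (3.03 to 785). Ubxn2a and Bola1 had 1 control read each and 26 and 22 knockout reads, with ratios of 24.6 (4.04 to 1009) and 20.8 (3.37 to 860). A second Ubxn2a region, within the gene, had 2 and 5 reads, a ratio of 2.37 (0.39 to 24.9).

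A pair of cytokine receptor genes was in this group. Il3ra, the alpha chain of the interleukin-3 receptor (chromosome 14, 14345892 to 14346318, upstream), had 2 control and 28 knockout reads, a ratio of 13.3 (3.34 to 115). Crlf2, a subunit of the receptor for thymic stromal lymphopoietin (chromosome 5, 109557658 to 109558552), had 3 and 36 reads, a ratio of 11.4 (3.59 to 57.7). A second listed region of Crlf2, upstream of its start site, had 1 and 13 reads, a ratio of 12.3 (1.85 to 523). A second region of 1700028E10Rik had 5 and 15 reads, a ratio of 2.84 (0.98 to 9.99), against 3 and 34 reads, a ratio of 10.7 (3.37 to 54.6), in the region ranked here. In the 10 regions ranked by log2 ratio, the lower counting limit was above 2. Without the pseudocount, regions with a single control read rank higher: Atxn10, Cfap36 and 2510002D24Rik, each with 1 and 16 reads (15.2, 2.35 to 635), and Tmem19, with 1 and 15 (14.2, 2.19 to 598), had higher ratios than Il3ra.

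The 10 genes named for the lowest log2 ratios among regions with a mean at or above the median were Akr1c13, Jagn1, Zfp709, 1810014B01Rik, Slc2a12, Zfp59, Ahi1, Cdc23, Fbxw17 and Lair1, with ratios of 2.01 to 2.05. Akr1c13, Jagn1 and Zfp709 each had 8 control and 17 knockout reads (2.01, 0.82 to 5.39). Cdc23, a subunit of the anaphase-promoting complex, and Lair1, an inhibitory receptor of leukocytes, each had 6 and 13 reads (2.05, 0.73 to 6.58). Selenoi, also with 6 and 13 reads, was tied with these and left out by alphabetical order. Equal H3K9me3 in both libraries lay within the counting interval of each of these regions, but a second region of Zfp709, within the gene, had 9 and 30 reads, a ratio of 3.16 (1.46 to 7.56).

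**Figure D2:**
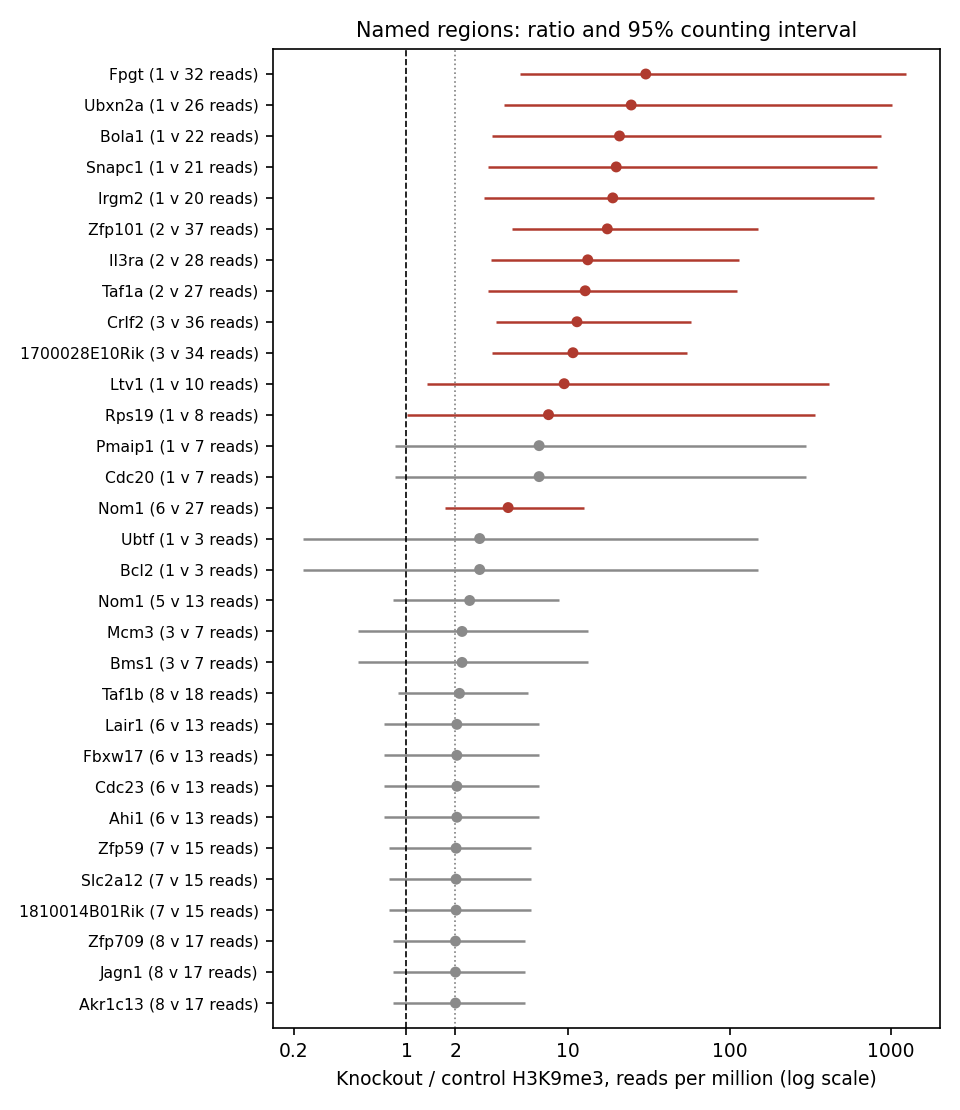
Ratio of knockout to control H3K9me3 in RPM (x axis, log scale) for the named regions, with the control and knockout reads of each beside its gene on the y axis; points are ratios, bars are exact 95% counting intervals, the dashed line is a ratio of 1, the dotted line a ratio of 2, and red marks intervals above 1. The intervals run from 5.06 to 1234 at Fpgt and include 1 for Taf1b, which had 8 and 18 reads.

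Of 15 genes for the machinery of RNA polymerase I, which transcribes ribosomal RNA, 7 had a listed region (46.7%, 95% interval 21.3 to 73.4): Taf1a, Taf1b, Znrd1, Rrn3, Polr1e, Ttf1 and Ubtf. Their nearest regions held 28 control and 129 knockout reads together, a ratio of 4.36 (2.88 to 6.82), and the interval lay above 1 for Taf1a, Znrd1 and Rrn3. For this and every other list, the selection forces a joint ratio above 2. Over the whole table the joint ratio was 3.43, and the interval lay above 1 for 21.1% of the regions. These values are not matched on reads, and a region with more reads reaches an interval above 1 more easily. A joint ratio also weights genes by their reads, and Znrd1 and Taf1a held the most knockout reads of this list. Taf1a, a subunit of the selectivity factor SL1, had 2 and 27 reads at chromosome 1, 183389079 to 183389618, a ratio of 12.8 (3.21 to 111). Znrd1, a polymerase subunit, had 9 and 47 reads, a ratio of 4.94 (2.40 to 11.5), with 1 and 4 reads in a second region (3.79, 0.37 to 187), and the initiation factor gene Rrn3 had 6 and 23 reads, a ratio of 3.63 (1.44 to 10.9). Ubtf, the upstream binding factor, had 1 and 3 reads, a ratio of 2.84 (0.23 to 149).

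Taf1b and Nom1 had been named in advance because the study singled them out on these samples, so their presence in the table is not independent evidence. The share and joint ratio of the RNA polymerase I list include Taf1b, and those of the nucleolus and ribosome assembly list include Nom1. Taf1b, another SL1 subunit, had 8 control and 18 knockout reads at chromosome 12, 24498735 to 24499231, within the gene, a ratio of 2.13 (0.88 to 5.66). Nom1, a nucleolar protein gene, had 6 and 27 reads in a region that spans its start site at 29434667 (chromosome 5, 29434220 to 29434737), a ratio of 4.26 (1.72 to 12.6). A second Nom1 region within the gene (29435268 to 29436024) had 5 and 13 reads, a ratio of 2.46 (0.82 to 8.82).

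Of 50 genes of the nucleolus and of ribosome assembly, 14 had a listed region (28.0%, 16.2 to 42.5), with 29 control and 133 knockout reads together, a ratio of 4.34 (2.89 to 6.73). The interval lay above 1 for 6 of them: Nol6, Nom1, Nop14, Ltv1, Ebna1bp2 and Sbds. Ltv1, an assembly factor of the small ribosomal subunit, had the highest ratio of the list (1 and 10 reads, 9.47, 1.35 to 411), and Bms1 the lowest (3 and 7 reads, 2.21, 0.50 to 13.2). Cytoplasmic ribosomal protein genes had a listed region in 7 of 40 cases (17.5%, 7.34 to 32.8), with 14 and 56 reads together, a ratio of 3.79 (2.08 to 7.37). Among these, Rps19 was highest (1 and 8 reads, 7.57, 1.02 to 336). For comparison, 1195 of the 21900 RefSeq protein-coding genes (5.46%) had a listed region. Whether a list is enriched was not tested, because that share includes genes without an H3K4me3 region, which could not be listed.

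Zinc finger genes with a Zfp symbol had a listed region in 62 of 394 cases (15.7%, 12.3 to 19.7). Their nearest regions held 201 control and 754 knockout reads, a ratio of 3.55 (3.04 to 4.17), and the interval lay above 1 for 20 of the 62. Ratios ran from 2.01 at Zfp709 to 17.5 at Zfp101. Members of this family can be near-identical, and the treatment of multiply mapped reads is not known, so single values are uncertain. None of the 1107 olfactory receptor genes and none of the 39 clustered protocadherin genes had a listed region.

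Of 40 regulators and markers of haematopoietic stem and progenitor cells, only Ly6a, which encodes Sca-1, had a listed region, with 1 control and 4 knockout reads (ratio 3.79, 0.37 to 187). Of 14 B lymphoid genes, only Dntt, a polymerase of antigen receptor rearrangement, had one, with 2 and 6 reads (ratio 2.84, 0.51 to 28.8). No region was listed for 21 myeloid, 14 T and NK cell or 16 erythroid and megakaryocyte genes. The same held for 39 Hox genes, 30 imprinted genes, 24 germline genes and 16 housekeeping controls. A gene missing from this table of selected regions may have had no region near its start site, no control read, or a ratio of 2 or less, so its absence gives no level.

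Of 21 p53 target and apoptosis genes, 5 had a listed region (23.8%, 8.22 to 47.2), with 6 control and 26 knockout reads together, a ratio of 4.10 (1.65 to 12.2). The interval of no single gene lay above 1; Pmaip1, which encodes Noxa, was highest (1 and 7 reads, 6.63, 0.85 to 299) and Bcl2 and Bcl2l11 were lowest (1 and 3 reads each, 2.84, 0.23 to 149). A second region of Bcl2 had 1 and 6 reads, a ratio of 5.68 (0.69 to 261). Of 30 cell cycle genes, 5 were listed (16.7%, 5.64 to 34.7), with a joint ratio of 3.70 (1.88 to 7.96). The ratio was highest at Cdc20 (1 and 7 reads, 6.63, 0.85 to 299) and lowest at Mcm3 (3 and 7 reads, 2.21, 0.50 to 13.2), and the interval lay above 1 for Plk1 (5 and 23 reads, 4.36, 1.62 to 14.7).

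Of 24 genes for writers, readers and erasers of H3K9 methylation and of DNA methylation, 3 were listed (12.5%, 2.66 to 32.4): Atf7ip, Setdb1 and Dnmt3a. Atf7ip, a partner of the H3K9 methyltransferase Setdb1, had the highest knockout level of the table and is named here for that reason after its value was seen. It had 13 control and 77 knockout reads at chromosome 6, 136518957 to 136519755, within the gene, a ratio of 5.61 (3.09 to 11.0). Setdb1 had 2 and 9 reads, a ratio of 4.26 (0.88 to 40.5), and Dnmt3a had 1 and 4, a ratio of 3.79 (0.37 to 187). None of the 4 Kdm4 genes had a listed region, and the table holds no value that checks the deletion.

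**Figure D3:**
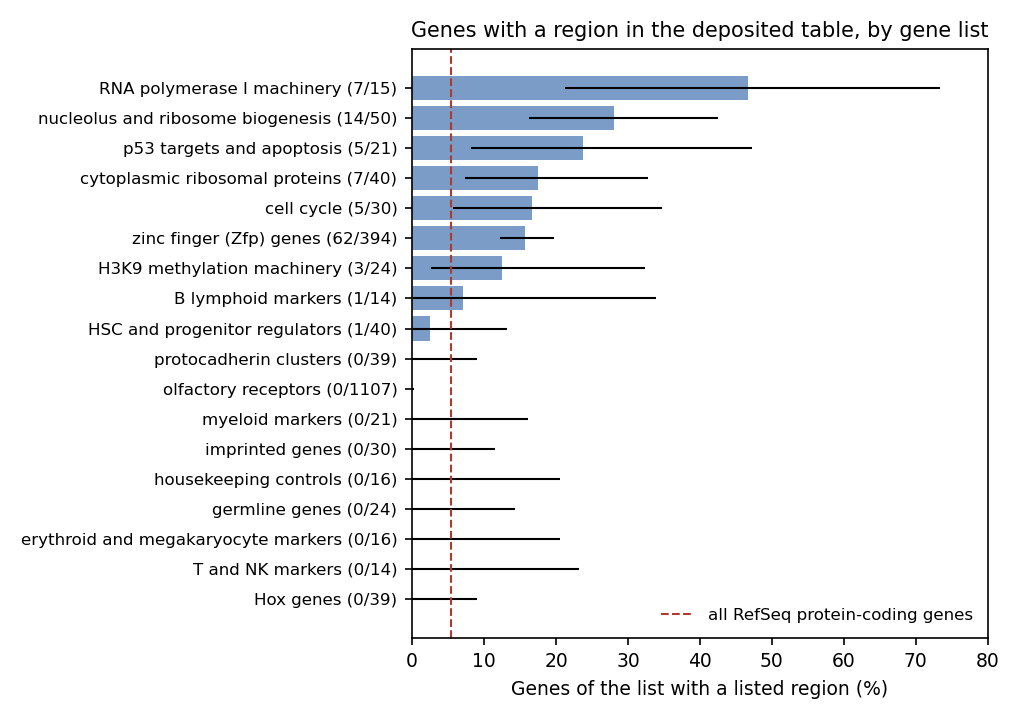
Share of each gene list with a region in the deposited table (x axis, percent; y axis, lists fixed before the data were examined, with listed and total genes); bars are shares, black lines exact 95% intervals, and the dashed line marks 5.46% of all RefSeq protein-coding genes. RNA polymerase I genes reach 46.7% and no Hox gene is listed. The shortest fixed lists, the Kdm4 genes and the pair of Taf1b and Nom1, are not drawn.

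Against random lists matched on mean H3K9me3, the median log2 ratio lay at the 87.0th percentile for RNA polymerase I genes, the 90.5th for the nucleolus and ribosome assembly, the 57.9th for ribosomal proteins, the 91.0th for p53 targets, the 42.4th for the cell cycle and the 79.7th for Zfp genes. All 6 lay inside the central 95% of the random lists, but p53 targets reached the 98.5th percentile with the mean over a gene's regions and Zfp genes the 99.1st with lists matched on width. Regions centred within 500 bp of the start site (652) and further away (729) had median ratios of 3.12 and 2.84; their median log2 ratio was 1.26 in both, a value that regions with 1 control and 4 knockout reads share. Across regions, which are not independent replicates, the log2 ratio had a Spearman's rho of 0.079 with H3K4me3 height and 0.050 with width. In regions with a mean at or above the median these were 0.133 and 0.054, and without the pseudocount, over all regions, 0.108 and 0.079.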

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

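Alternatives were listed before the data were examined, except those for the counting intervals, which were chosen after seeing the data. No replicate could be left out and no paired analysis was possible because each group has 1 library. The pseudocount moved the median log2 ratio of 1.26 to 1.58 when 10 times smaller and to 0.65 when 5 times larger, and regions with a mean at or above the median gave 1.35. Because the table holds only ratios above 2, scalings that equalize both libraries over it push the typical region to 0 or below by construction: the median was 0 after centring, -0.13 after quantile normalization and -0.13 with equal sums, and 17 of the 32 named regions fell below 0 under each. The count of 599 regions at least 2-fold higher became 72, 62 and 44 under these scalings, 273 with the larger pseudocount, 259 at a fold of 3, 916 with no filter on the mean and 313 with a mean at or above the 75th percentile; the count lower stayed at 0 throughout. Of 48 recomputed list percentiles, 46 stayed inside the central 95% of the random lists; the exceptions were p53 targets at the 98.5th percentile with the mean over a gene's regions and Zfp genes at the 99.1st with lists matched on width, and the cause was not tested. The 292 regions with an interval above 1 became 143 with 99% intervals. The upper part of the table by H3K4me3 height holds 691 regions. No regions overlapped or touched. A window of 5 kb could add none, because the table holds only regions centred within 1 kb of a start site. All 64 recomputed values of named regions under both pseudocounts stayed inside their counting intervals, but these are wide and show little about stability. At Fpgt the log2 ratio of 3.97 became 4.79 with the smaller pseudocount and 2.56 with the larger. Depth limits single values: 803 regions hold fewer than 10 reads in both libraries together.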

Other observations

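The 3 gene lists in this paragraph were drawn up after the table had been read, so their counts are descriptions and not tests; the 3 tests in the next paragraph were stated before their results were seen. Of 20 cytosolic aminoacyl-tRNA synthetase genes, 6 had a region (30.0%, 95% interval 11.9 to 54.3): Aars, Dars, Farsb, Nars, Tars and Yars, with 14 control and 60 knockout reads together, a ratio of 4.06 (2.24 to 7.86). Farsb had 3 and 23 reads, a ratio of 7.26 (2.19 to 37.8). Of 78 mitochondrial ribosomal protein genes, 11 had a region (14.1%, 7.26 to 23.8), with a joint ratio of 4.40 (2.44 to 8.48), and the interval lay above 1 for Mrpl15. Of 40 interferon-inducible genes, 11 had a region (27.5%, 14.6 to 43.9), among them Irgm2, Ifit2, Oas1a, Oas1b, Trim25 and Bst2, with a joint ratio of 4.09 (2.55 to 6.83). Their median ratio was 3.08, and the interval lay above 1 for Irgm2 and Trim25 only. Irgm2 held 1 of the 22 control reads and 20 of the 95 knockout reads of this list. Aim2, a cytosolic DNA sensor outside this list, had 15 and 53 reads, a ratio of 3.35 (1.86 to 6.39).

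Knockout reads exceeded control reads in the listed regions, and the table was selected for that. Counting noise picked out by the selection on the ratio does not account for the whole excess: in the 897 regions whose totals allowed more than 1 outcome under that selection, 10484 knockout reads were found, against a mean of 9833 (SD 19.2) and a highest value of 9906 in 10000 draws with equal rates. A single scale factor with counting error only is also argued against, because the dispersion around 1 common fold (2.70, range of the fit 2.54 to 2.87) was 1.18, above the highest of 10000 draws, 1.13, and the fold under the selection was 1.54 (1.22 to 1.94) for regions with 7 to 9 reads, 2.27 (2.04 to 2.52) with 10 to 19 and 3.19 (2.95 to 3.44) with 20 to 106. The excess may still come in part, or as a whole, from noise that is independent from region to region, beyond counting error. The draws above held counting error only, so they cannot exclude such noise picked out by the selection. Neighbouring listed regions of different genes 5 to 100 kb apart showed no shared excess (Spearman's rho = -0.0058 over 83 pairs, central 95% of shuffles -0.214 to 0.209). Pairs of regions of 1 gene showed none either (0.085 over 52 pairs, -0.274 to 0.271). What stays open is such noise alone, loss of the demethylases, or another difference between these 2 libraries, such as the yield of the immunoprecipitation. Such noise together with either of the others also stays open. The causes cannot be told apart, because each group has 1 library and the regions that fell or did not change are not analysed here.

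The X chromosome held 19 of the 1381 regions (1.38%), while 4.41% of RefSeq protein-coding genes lie on it. Chromosome 13 held 75 regions (5.43%, against 3.79% of genes) and chromosome 18 held 48 (3.48%, against 2.34%). Other chromosomes differed in both directions, such as chromosome 12 (4.20% against 3.10%) and chromosome 14 (3.11% against 3.89%). These shares were not tested against each other. The region shares also count genes that are not protein-coding, and genes without an H3K4me3 region or a control read could not be listed. There were 85 genes with 2 listed regions, among them Nom1, Znrd1, Crlf2 and Heatr1.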
